A study of Drosophila melanogaster with 3 samples.

How the data were processed

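Chromatin immunoprecipitation sequencing of su(Hw)-eGFP was carried out in 3 biological replicates of whole Drosophila melanogaster embryos of 0 to 24 hours, mixed in sex. Per the labels, chromatin was sonicated, fragments were 200 to 800 bp long and the antibody was directed against GFP, although the antibody field of the labels names su(Hw). The authors deposited peak lists in 2 builds, dm6 and dm3: 1 list per replicate, 1 pooled list and 1 list thresholded by the irreproducible discovery rate (IDR). The peak caller, its version, the aligner, the IDR threshold and the read depth are not given in the sources used here. A control alignment named in the labels was not analysed here. Replicate lists were called per sample. Each unthresholded list held 30000 peaks, weak ones included, and thus had a fixed length, so the number of peaks in a replicate list says nothing about its depth.

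The deposited lists give each peak an interval, a summit, a signal and a significance value. The signal is the authors' peak caller's own value, never negative, on a scale that the deposited files do not define; it was used only to rank and describe peaks within a list. The significance column holds −log10 q-values as deposited by the authors. It could not rank the strong peaks, since 4732 of the 6127 thresholded dm6 peaks shared the highest value. The p-value column of the deposited files held a constant. The thresholded list held the 6127 strongest peaks of the pooled list by signal, in dm6, and the 5463 strongest in dm3. No pair of replicate lists shared an identical peak, so the 3 were treated as separate libraries. Among the thresholded dm6 peaks, 185 repeated the interval of another peak with a different summit, and summits were never closer than 199 bp.

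The reference was Release 6 of the genome with Ensembl annotation release 115. No dm6 peak lay beyond the end of its reference chromosome, and dm6 coordinates were used throughout; dm3 lists were compared only with each other, and no coordinates were converted. Transposable elements of the annotation were left out of the gene classes. Coordinates are 1-based. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

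Summits matched when no more than 200 bp apart. Replicate overlap was the percent of the strongest 6127 peaks of a replicate matched by the strongest 6127 of another, averaged over the 6 ordered pairs. Random placements, 1000 per test, drew positions from the sequenced bases of each summit's own chromosome. A summit was assigned to the first class that applied among promoter, coding exon, other exon, intron and intergenic. The second background was the 20682 of 23873 unthresholded pooled peaks that lay over 1 kb from every thresholded summit. Sequences were searched within 100 bp of the summit on both strands and compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 4 motifs. A gene had a peak when a thresholded summit lay in its body or within 1 kb. The 16 gene lists were compared with 10000 random lists matched on gene length in 10 bins, and 10 listed symbols were looked up under their current names. Adjusted values under 0.05 were called. The permutation tests treat summits or genes as independent, and intervals cover counting error only.

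Lists, motifs, windows and tests were fixed before the data were examined. So was the rule for named genes: genes of the 15 strongest peaks (the gene that holds the summit, else that of the nearest start), up to 4 members per list with the strongest summit (6 for lists that passed), 10 fixed loci, the 5 genes with most summits, and the 5 peaks whose ranks differed most between replicates. For these ranks, a replicate list without a summit within 200 bp counted as past its last rank. Segmentation genes without a summit were named after their values were seen, as were the sequences TATCGATA and GGTCACAC. Alternatives changed the matching distance, peak set, background, promoter window, motif window, gene assignment, length matching and build, and left out each replicate in turn. For results on the thresholded list, leaving out a replicate meant keeping the thresholded peaks with a top-ranked peak in each of the other 2 replicates; the list itself still came from all 3, and such a set also carries a filter that the main set does not. Merging summits within 500 bp, 50 length bins and 1 list member per 20 kb were chosen after seeing the data.

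The functions were tested on simulated data. For the location test, a simulated promoter share of 46.0% was recovered as 44.9% over 3000 summits, and 3.50% of 200 unchanged sets passed 0.05. For the matching of summits, 80.1% was simulated and recovered. For gene lists of 40 genes, 4.60% of 500 random lists and 2.80% of 500 lists of long genes passed 0.05, while all of 200 lists given more summits did.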

Results

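The series measured where su(Hw), a zinc finger protein that binds chromatin insulators of Drosophila melanogaster, sat on the genome of whole embryos. Chromatin came from a transgenic line that carries su(Hw) fused at its C terminus to enhanced green fluorescent protein, collected 0 to 24 hours after egg laying from both sexes together, and was immunoprecipitated with an antibody against the tag. All 3 samples were biological replicates of this 1 group, so the design gave no contrast between conditions. The comparisons were between replicates, between the thresholded peaks and the weaker peaks of the same list, and between peaks and annotated genes or sequence. Each replicate list and the pooled list held 30000 peaks, weak ones included, and the thresholded list held 6127 peaks in the dm6 build. The number of reads behind the lists is unknown, and the intervals of shares below are exact binomial (Clopper-Pearson) 95% intervals. These and the intervals of odds ratios cover counting error only, and peaks are not independent of each other.

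The first comparison asked how far the replicates recovered the same sites. Among the 6127 strongest peaks of each replicate, 78.9% ± 1.5 (SD over the 6 ordered pairs of 3 replicates) had a summit of the other replicate's strongest 6127 within 200 bp, against 1.83% for summits placed at random on the same chromosomes. This was 43.1-fold above the random level, with p = 0.002 in a two-sided permutation test, the smallest p that 1000 placements can give. Pairs of replicates ranged from 77.4% to 81.1%. The overlap was 91.9% ± 0.701 for the strongest 500 peaks and 60.1% ± 1.91 for all 30000. Of the 6127 thresholded peaks, 4249 (69.3%, interval 68.2 to 70.5) had a top-ranked peak, meaning one of the 6127 strongest, in all 3 replicates. A further 1338 (21.8%) had one in 2 replicates, 501 (8.18%) in 1 and 39 (0.637%) in none. The share found in all 3 replicates was 99.5% (98.6 to 99.9) among the strongest 613 peaks and 5.71% (4.01 to 7.85) among the weakest 613, which lie at the edge of the 6127 ranks counted. With the whole replicate lists of 30000 peaks in place of the strongest 6127, 97.2% (96.8 to 97.6) of all thresholded peaks and 94.5% (92.3 to 96.1) of the weakest 613 had a peak in all 3, against 3.36% of random placements. The thresholded list was made from these same 3 replicates, so its high shares in their lists follow at least in part from that choice. Random placements do not take this into account. Across peaks matched in both lists, Spearman's rho of the signal was 0.78 between replicates 1 and 2, 0.83 between 1 and 3 and 0.79 between 2 and 3. These correlations are across peaks of a list, which are not independent replicates.

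**Figure D1:**
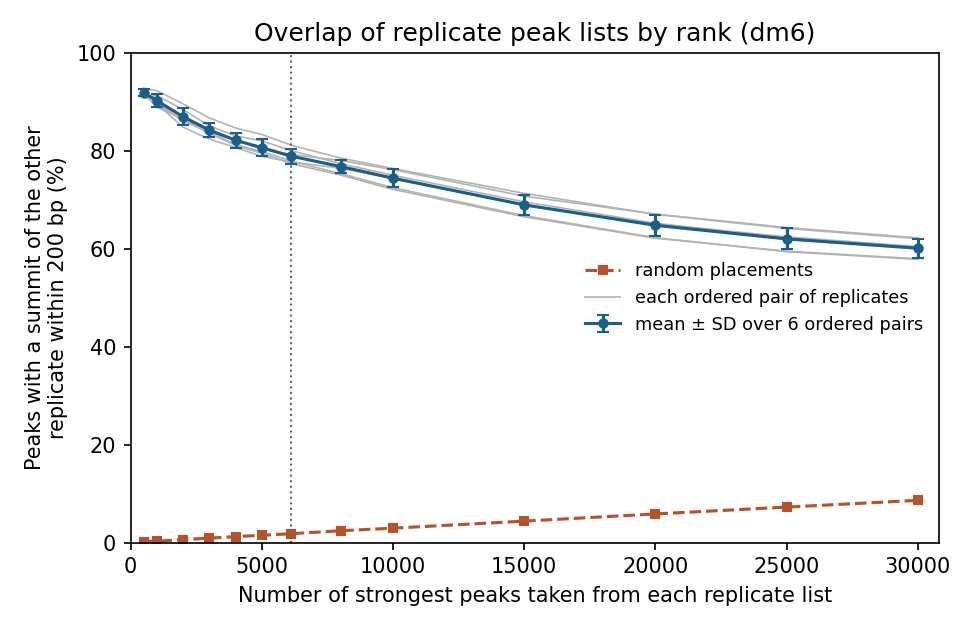
The vertical axis gives the percent of peaks with a summit of the other replicate within 200 bp, and the horizontal axis the number of strongest peaks taken from each replicate list. Circles are means ± SD over the 6 ordered pairs of replicates (grey lines), squares are random placements, and the dotted line marks 6127 peaks; the overlap falls from 91.9% at 500 peaks to 60.1% at 30000, above the random level throughout.

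The strongest peak of the list lay in an intron of siz on chromosome 3L, at 21049279 to 21050234 (dm6), with a pooled signal of 20808, and it ranked 1 in all 3 replicates. The next lay inside Mob2, a gene of the Mob family of kinase activators, in the promoter windows of CG11714 and Fuca, with a signal of 16607. The peak with rank 3 lay inside ush, in a promoter window of that gene, which encodes a partner of GATA transcription factors. It spanned 489867 to 490731 on 2L and ranked 2, 3 and 4 in replicates 1, 2 and 3. Rank 4 was an intergenic peak whose nearest gene start, 1582 bp away, was that of Loxl1. Rank 5 lay inside su(Hw) itself, outside its own promoter window and in that of its neighbour Polr2I. The remaining peaks of the strongest 15 lay in or next to CG32301, CG33453, Glut3, pyd, RapGAP1, CG33158, TER94, Cyt-b5, pnt and sm. Among these genes, pyd encodes a junctional scaffold protein of the ZO-1 type, TER94 the p97 ATPase and pnt an ETS transcription factor. All of the strongest 15 peaks were top-ranked in all 3 replicates, and no replicate placed any of them below rank 17. An exact match to the su(Hw) consensus lay within 100 bp of the summits at CG32301, CG33453 and Cyt-b5, and no match even with 1 mismatch at those of ush and su(Hw). The genes with the most thresholded summits in their bodies were kirre with 18, Dys with 15, CG1677 with 13, ush with 12 and Flo2 with 11. These are long genes, from 64341 bp for ush to 394149 bp for kirre.

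Summits were assigned to annotation classes to ask where in the genome the protein was recovered. Promoters, defined as 1000 bp upstream to 100 bp downstream of the start of a protein-coding transcript, held 3119 of the 6127 summits, or 50.9% (interval 49.6 to 52.2). Random placements on the same chromosomes gave 12.4% ± 0.428 (SD over 1000 placements), a 4.11-fold difference. The fold depended on the promoter window: it was 6.59 with a window from 500 bp upstream to 50 bp downstream (43.5% against 6.60%) and 2.59 with one from 2 kb upstream to 500 bp downstream (61.4% against 23.8%). Coding exons held 65 summits, 1.06% (0.820 to 1.35) against 14.6% at random, and 0.655% with summits merged within 500 bp, an alternative chosen after seeing the data. Introns held 29.3% against 39.5%, intergenic sequence 13.1% against 26.4% and other exons 5.58% against 7.01%. For each of these 5 classes the two-sided permutation p was 0.002, the smallest that the placements can give. A second background was 20682 unthresholded peaks of the pooled list that lay over 1 kb from any thresholded summit. Of these, 23.9% were at promoters, so that the odds ratio of thresholded against unthresholded peaks was 3.31 (95% interval 3.12 to 3.51). Introns were again less frequent among thresholded peaks, with an odds ratio of 0.452 (0.425 to 0.480), and so were coding exons, with 0.140 (0.109 to 0.180). Against this background the intergenic share was not lower: 13.1% stood against 12.3%, with an odds ratio of 1.08 (0.990 to 1.17) and p = 0.0862 in Fisher's exact test.

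**Figure D2:**
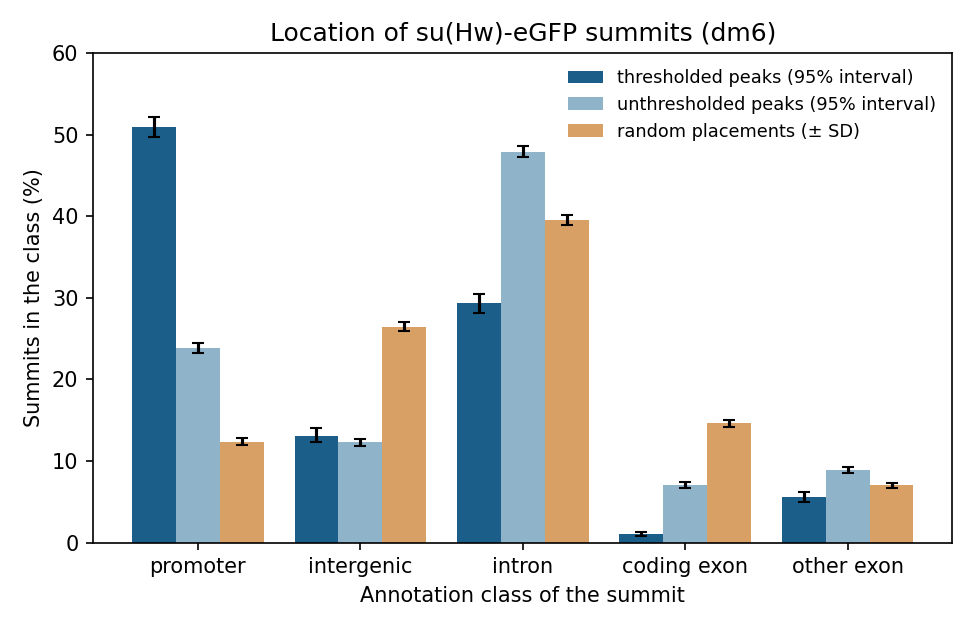
Percent of summits in each annotation class for thresholded peaks, unthresholded peaks over 1 kb from them (both with 95% intervals) and random placements (± SD over placements). Promoters hold 50.9% of thresholded summits, 23.9% of unthresholded ones and 12.4% of random positions, and coding exons hold 1.06% of thresholded summits.

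The 12-base consensus YRYTGCATAYYY of su(Hw) was searched within 100 bp of each summit. It lay, as an exact match on either strand, at 432 thresholded peaks (7.05%, interval 6.42 to 7.72) and at 1.74% of unthresholded peaks. The odds ratio was 4.29 (3.72 to 4.95), with an adjusted p = 2.98e-85 by two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over 4 motifs. Its centre lay a median of 16.5 bp from the summit, and 89.6% of the 432 peaks had it within 50 bp. With 1 mismatch allowed the shares were 21.6% and 9.28%, and with the core TGCATA alone 23.5% and 15.1%. Windows 2 kb from the thresholded summits held an exact match in 0.277% of cases. Pairs of CGATA on either strand within 40 bp of each other were searched as the sequence bound by the insulator protein BEAF-32. They were at 8.86% of thresholded and 4.06% of unthresholded peaks. The odds ratio was 2.30 (2.05 to 2.57), with an adjusted p = 1.48e-44 by the same exact test. Thresholded peaks also lay at promoters more often than unthresholded ones (50.9% against 23.9%). No comparison of these pairs within promoters is given here, so the difference cannot be separated from that in location. A single TATCGATA reads CGATA on both strands and so also counted as a pair. TATCGATA, picked after the data were seen, was at 4.18% of thresholded and 1.52% of unthresholded peaks. The GAGA factor sequence GAGAGAG (4.16% against 3.68%, adjusted p = 0.116) and the Zelda sequence CAGGTAG (0.930% against 0.953%, adjusted p = 0.940) did not pass the exact test.

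The consensus and the location both moved with peak strength. The strongest 613 peaks carried the consensus with up to 1 mismatch in 50.1% of cases (46.0 to 54.1), and the weakest 613 in 14.0% (11.4 to 17.0). Exact matches were at 20.2% and 4.08% of these peaks. BEAF-32 pairs went the other way, with 2.77% (1.62 to 4.40) of the strongest and 10.4% (8.13 to 13.1) of the weakest peaks. TATCGATA, which counted among these pairs, was at 1.47% of the strongest and 5.22% of the weakest peaks. Intergenic summits made up 29.0% of the strongest and 7.83% of the weakest 613, and promoter summits 38.5% and 51.7%. Within the thresholded list the consensus with up to 1 mismatch was at 11.5% (10.4 to 12.7) of promoter summits and at 32.0% of all others (p = 8.33e-87, two-sided Fisher's exact test). It was at 40.2% (36.8 to 43.7) of intergenic and 29.6% (27.5 to 31.8) of intronic summits.

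**Figure D3:**
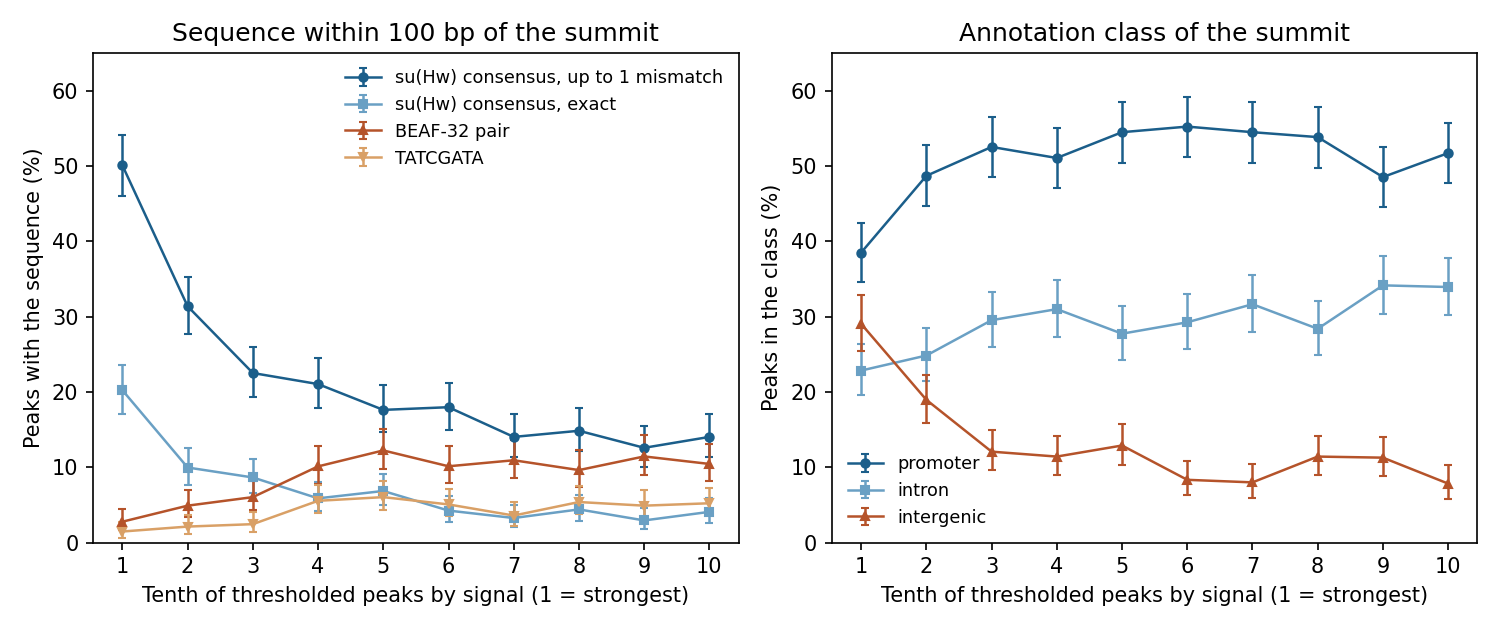
Thresholded peaks in 10 groups of 612 or 613 by signal, strongest at the left, with the percent that carries each sequence within 100 bp of the summit (left panel) and the percent in each annotation class (right panel); bars are 95% intervals. The consensus with up to 1 mismatch falls from 50.1% to 14.0% and intergenic summits from 29.0% to 7.83%, while BEAF-32 pairs go from 2.77% to 10.4%.

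The X chromosome held 1056 of the 6101 summits on the 5 large arms, 17.3% (16.4 to 18.3), and made up 17.8% of their length (p = 0.357, two-sided exact binomial test). Against the unthresholded peaks, of which 19.8% were on X, the thresholded share was lower (p = 1.07e-05, Fisher's exact test), so the call depended on the background. The arms carried 44.9 (X) to 47.1 (2L) peaks per Mb. Chromosome 4 carried 18.5 per Mb (25 peaks, 12 to 27.3) and the assembled Y 0.273 per Mb (1 peak). Thresholded summits lay near each other more often than random placements: 62.5% had another within 5 kb, against 36.9% at random (permutation p = 0.002, the smallest the placements can give). Within 1 kb the shares were 29.6% and 8.78%, and within 20 kb 92.0% and 84.0%. Part of this came from summits 199 to 300 bp apart, which made up 738 of the 6120 gaps. With summits no more than 500 bp apart merged, 5342 sites remained and 50.1% had a neighbour within 5 kb, against 33.0%.

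A thresholded summit lay in the body or within 1 kb of 5182 of 13968 protein-coding genes (37.1%, interval 36.3 to 37.9), and in a promoter window of 3685. Gene lists fixed before the data were examined were compared with random lists of the same size matched on gene length. Genes of ribosomal proteins had a summit in 69 of 85 cases (81.2%, 71.2 to 88.8) against 28.2% ± 4.78 (SD) in matched lists, and in 87.1% against 54.2% with a 5 kb flank. Their strongest sites were at RpS21, in its promoter window with rank 52 and an exact consensus, and near RpS15Aa and RpLP0. The strongest summits of RpS15Aa and RpLP0 were intergenic, past the 3′ ends of these genes. Of the 85 genes, 68 had a summit in a promoter window. RpL28, RpL7 and RpL23A had peaks of rank 574, 601 and 840. Chemosensory receptor genes had one in 14 of 179 cases (7.82%, 4.34 to 12.8) against 32.8% ± 3.42. The strongest of these few were near Or47a, Or43a, Gr97a, Or92a, Ir68b and Or88a. The share of chemosensory receptor genes was 2.23% against 25.5% in promoter windows and 30.7% against 58.4% with a 5 kb flank. Heat shock genes had one in 12 of 15 cases (80.0%, 51.9 to 95.7) against 34.8% ± 12, among them Hsp27, Hsp83, Hsc70-5, Hsc70-4 and Hsp26, whose summit is shared with Hsp67Ba. These 3 of 16 lists passed, each with an adjusted p = 0.00107 (two-sided permutation test with 10000 matched lists, Benjamini-Hochberg over the 16 lists, from the smallest p of 0.0002 that these can give). The heat shock call was lost in 4 smaller sets of peaks: the strongest 3063 (40% against 19.4%), the 4249 found in all 3 replicates (46.7% against 26.2%), the 4691 found in both replicates 2 and 3 (53.3% against 28.5%, adjusted permutation p = 0.285) and the 4808 found in both replicates 1 and 3 (46.7% against 28.5%, adjusted permutation p = 0.435). Each of the last 2 sets drops 1 replicate and also adds a filter on the other 2, and the thresholded list itself was made with all 3, so these losses cannot be assigned to a replicate. The call was kept among the 4586 peaks found in both replicates 1 and 2 (66.7% against 27.5%, adjusted permutation p = 0.0128) and among the 5342 merged sites (80.0% against 34.7%, adjusted permutation p = 0.00533). Some heat shock genes lie close together. With 1 list member per 20 kb, 7 of 9 had a summit (77.8% against 38.9%, adjusted permutation p = 0.0352).

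The other 13 lists did not pass in the main setting. Segmentation genes, which pattern the early embryo, had a summit in 6 of 27 cases against 46.2% in matched lists (adjusted permutation p = 0.0688). The members with one included nkd, Dll, cad and nanos, while eve, ftz, hb, Kr, en and wg had none. Neurogenesis genes had one in 8 of 28 cases (adjusted permutation p = 0.159), with the strongest at brat, pros, numb and N. Hox genes had one in 3 of 8 (adjusted permutation p = 0.375), and the peak in an intron of Antp had rank 33. Neuronal function genes (27 of 50, adjusted permutation p = 0.586) included Dscam1, nompC, Syn and Atpalpha. Ecdysone genes (14 of 22, adjusted permutation p = 0.808) included Eip75B, whose intronic peak had rank 29 and an exact consensus, and shd, Eip78C and EcR. Muscle genes (10 of 25, adjusted permutation p = 0.375) included Zasp52, twi, how and Msp300. Germline and oogenesis genes (12 of 30, adjusted permutation p = 0.593) included Rbp9, mei-P26, orb and pum. Polycomb and trithorax genes (16 of 27, adjusted permutation p = 0.586) included ash1, Trl, ph-p and osa, and the ash1 summit lay outside that gene, in the promoter window of CG14100. Proteasome subunits (17 of 40, adjusted permutation p = 0.219) included Rpn13, Rpn5, Rpt1 and Prosbeta5. Cuticle proteins (21 of 95, adjusted permutation p = 0.375) included Cpr97Ea, Cpr49Ae and the pair Cpr62Ba and Cpr62Bb, which share a summit. Testis genes (3 of 24, adjusted permutation p = 0.219) were mia, topi and bol, and the topi summit lay outside that gene, in the promoter window of RpS29. Dosage compensation genes (4 of 8, adjusted permutation p = 0.90) were roX2, msl-2, Clamp and msl-3. The roX2 summit lay outside the gene, in the promoter window of nod. Those of Clamp and msl-3 were not top-ranked in all 3 replicates. Insulator proteins (11 of 24, adjusted permutation p = 0.935) included su(Hw), Chro, Trl and Cp190. With promoter windows only, cuticle proteins (3.16% against 20.7%, adjusted permutation p = 0.00107) and testis genes (4.17% against 21.7%, adjusted permutation p = 0.0176) were also below their matched lists. With a 5 kb flank, segmentation genes (29.6% against 65.3%, adjusted permutation p = 0.00107), neurogenesis genes (35.7% against 62.7%, adjusted permutation p = 0.0176) and testis genes (25% against 54.2%, adjusted permutation p = 0.0176) were below theirs, and so were cuticle proteins when lists were matched on gene plus intergenic span (22.1% against 37.2%, adjusted permutation p = 0.0136).

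**Figure D4:**
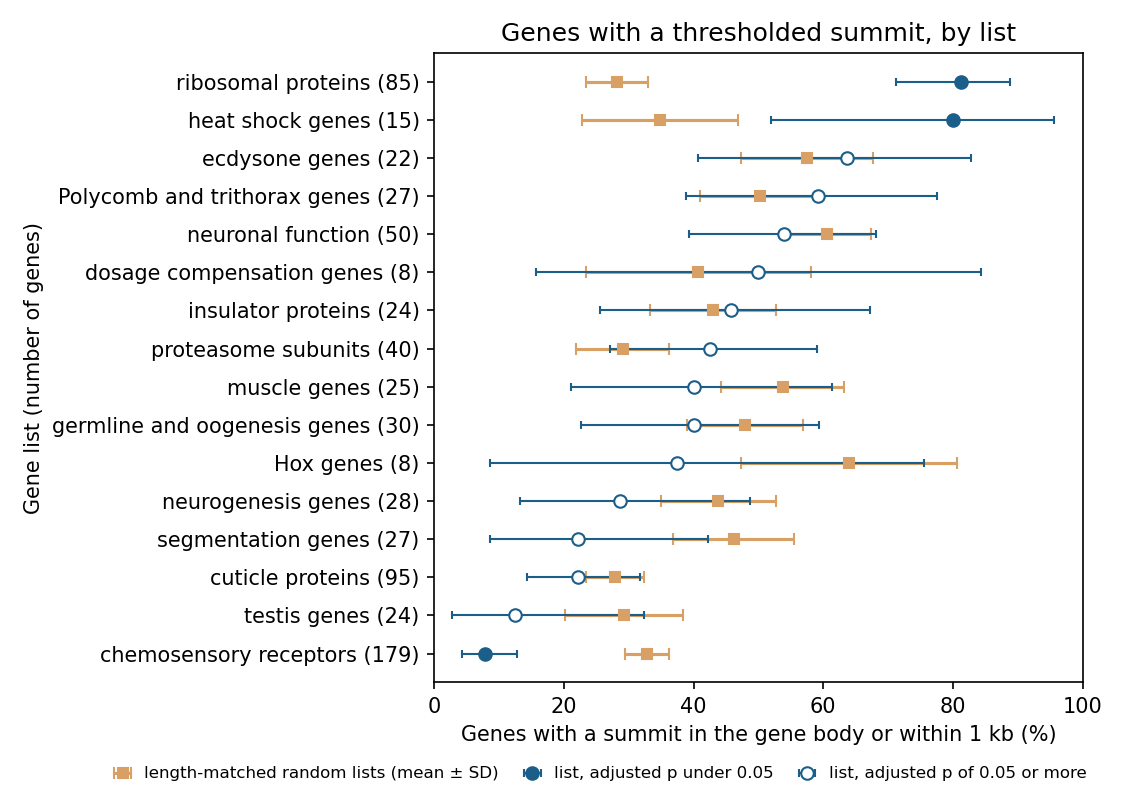
Percent of the genes of each list with a thresholded summit in the gene body or within 1 kb (circles, 95% intervals) beside length-matched random lists (squares, mean ± SD). Ribosomal protein and heat shock genes, at 81.2% and 80.0%, lie above their matched lists and chemosensory receptors, at 7.82%, below theirs.

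Loci fixed in advance included the y and ac genes, which flank an endogenous su(Hw) insulator. The strongest peak at y spanned 361290 to 362045 on X, just past the end of the gene at 361245. It had rank 93, an exact consensus and ranks of 89, 93 and 104 in replicates 1, 2 and 3. No thresholded summit lay in ac or within 1 kb of it. Rbp9 had 5 summits in its body, the strongest with rank 427. Of the genes of proteins that act with su(Hw) at insulators, Cp190 had 1 summit at its promoter with rank 1108. The single summit of mod(mdg4), with rank 1450, lay in its body and outside its own promoter window. CTCF, which encodes another insulator protein, had 1 promoter summit with rank 2413. No consensus with up to 1 mismatch lay within 100 bp of the summits at these 3 genes. In the bithorax complex, Ubx had 1 summit, past its 3′ end, with rank 4669. No thresholded summit lay in abd-A or Abd-B or within 1 kb of them. The peak of rank 8, given above under Glut3 by its nearest gene start, lay between these genes, over 1 kb from each. It spanned 16798340 to 16799222 on 3R, between Ubx (to 16734426) and abd-A (from 16807214), and matched the consensus with 1 mismatch. The peak at su(Hw) spanned 14307615 to 14308772 on 3R, with its summit at 14308104, inside the gene at 485 bp from its nearest transcript start. Its pooled signal was 14985 and it ranked 5, 4 and 5 in the replicates.

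**Figure D5:**
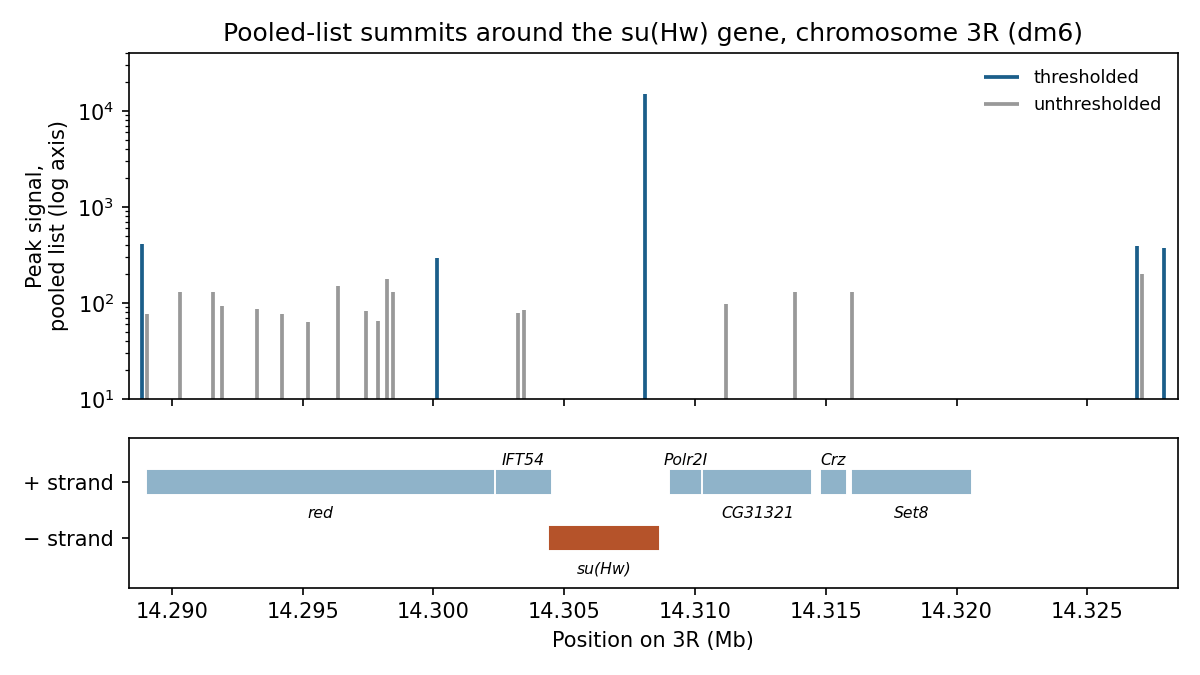
Summits of the pooled list around su(Hw) on chromosome 3R (dm6), with position in Mb on the horizontal axis and peak signal on a log axis; blue lines are thresholded and grey lines unthresholded summits, and boxes below are protein-coding genes by strand within 10 kb of the su(Hw) summit. The su(Hw) summit has a signal of 14985, and the next highest summit within 10 kb has 293.8.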

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

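The dm3 lists also cover heterochromatic and unplaced scaffolds that are separate from the main chromosomes in that build, and 5 thresholded peaks lay there. The number expected there was not computed. Of these, 3 were on the 2R heterochromatin scaffold, the strongest with rank 18 of the pooled dm3 list. A single peak was on the 3R heterochromatin scaffold and a single one on the set of unplaced sequences. Each of these 3 scaffolds also had peaks in all 3 replicate lists. The dm3 sequence was not used here, so neither genes nor sequence under these peaks were examined. No coordinates were converted, so whether the same sites are among the dm6 peaks is unknown.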

How the results depend on the processing

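Merging summits within 500 bp, 50 length bins and 1 list member per 20 kb were chosen after seeing the data. Against random placements, the promoter, intergenic, intron and coding exon shares and the clustering of summits kept their direction and their call under every alternative run, as did the su(Hw) and BEAF-32 sequences against unthresholded peaks and the ribosomal protein and chemosensory lists. In all, 130 of 161 alternatives of the main results kept direction and call or, without a test, stayed within their spread or within 1.5 times for counts; in 13 of these the value or its fold over the background still moved by over 1.5 times. These were other promoter windows, backgrounds, forms of the consensus, clustering distances and ways to assign summits to genes, and the coding exon share with merged summits. Further, 497 of 624 counts of summits at the 78 genes named by gene list, fixed locus or number of summits stayed within 1.5 times. Except for replicate overlap and rho, leaving out a replicate also added the filter of a top-ranked peak in both others, within a list made from all 3, so those values do not show the effect of a replicate alone. The causes of the changes below were not tested. No paired analysis was possible because the design has 1 group. The read depth is unknown, so the depth at which weak sites would be missed cannot be given.

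Replicate overlap was 72.7% with summits within 100 bp, 82.7% within 500 bp, 82.6% with 1 bp of shared interval and 73.3% with 50% reciprocal overlap. It was 84.1% for the strongest 3063 peaks and 60.1% for all 30000, and from 77.6% to 80.6% leaving out each replicate. The share of thresholded peaks found in all replicates was 62.9%, 74.6%, 74.3% and 58.7% under the same 4 matching rules. It was 38.9% when each replicate list was limited to 3063 peaks, 97.2% with whole lists, and from 74.8% to 78.5% leaving out each replicate, where fewer replicates had to match. Mean rho was 0.86 at 500 bp and 0.89 as Pearson's r of log2 signal, and from 0.78 to 0.83 leaving out each replicate.

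Against unthresholded peaks the intergenic share of 13.1% turned from lower to not lower (background 12.3%). Against the same background the X share of 17.3% became lower (background 19.8%), and the dm3 lists gave 17.3% against 20.4%. With summits merged, the Zelda sequence stood at 0.955% against 0.953%. Genes with a peak numbered 3044 with the strongest 3063 peaks and 8273 with a 5 kb flank.

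The number of lists past the threshold, 3 in the main setting, was 5 with promoter windows only (cuticle proteins and testis genes added) and 6 with a 5 kb flank (segmentation, neurogenesis and testis genes added). Heat shock genes lost their call with the strongest 3063 peaks (40%) and with peaks found in all replicates (46.7%), and ranged from 46.7% to 66.7% leaving out each replicate with the added filter. Among lists that did not pass, the direction turned with promoter windows only for insulator proteins (25.0%), ecdysone genes (27.3%) and dosage compensation genes (25.0%). With a 5 kb flank it turned for insulator proteins (62.5%) and germline genes (70.0%). Matching on gene plus intergenic span turned it for neuronal function (54.0%), Hox (37.5%), muscle (40%) and germline genes (40%). Cuticle proteins turned with the strongest 3063 peaks (17.9%), proteasome subunits with peaks found in all replicates (20%), and dosage compensation genes under both (12.5% and 25.0%), with 25.0% to 50% leaving out each replicate.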

Other observations

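The test of a recognition sequence at su(Hw), the sequences TATCGATA and GGTCACAC, the other classes of noncoding genes and elements, the width of the su(Hw) peak, the comparisons of replicate support with other sites and in whole lists, and the search for strong peaks missing from another replicate were chosen after the results were seen. No biological explanation was tested against another group, since the design has 1 group.

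Of 5 classes of noncoding genes, small nuclear RNA genes and the class annotated as ncRNA had a thresholded summit nearby more often than random placements. Of 32 small nuclear RNA genes, 12 (37.5%, interval 21.1 to 56.3) had a thresholded summit within 500 bp, against 5.19% of random placements (7.22-fold; p = 0.002 in a permutation test, the smallest that 1000 placements can give). Of 3289 ncRNA genes, 404 had one (12.3% against 8.96%, 1.37-fold; permutation p = 0.002). Small nucleolar RNA genes had one in 25 of 269 cases (9.29% against 5.06%, permutation p = 0.110), tRNA genes in 22 of 290 (7.59% against 4.88%, permutation p = 0.126) and rRNA genes in 0 of 99 (interval 0 to 3.66, against 5.39%, permutation p = 0.248). The classes were not tested against each other. Annotated transposable elements had one less often than random placements, in 183 of 5889 cases (3.11% against 9.99%, permutation p = 0.002). Coordinates of repeated sequence, gene copies included, depend on how the authors placed reads, which is not given in the sources used here.

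Most promoter peaks carried no exact su(Hw) consensus, and neither did most other peaks. An exact match was at 2.95% of promoter summits and 11.3% of all other thresholded summits. After merging summits within 500 bp, 2610 promoter sites had no exact match. Of these, 68.4% (66.6 to 70.2) had a top-ranked peak in each of the 3 replicates, against 71.7% of all other sites (odds ratio 0.857, 0.762 to 0.963; p = 0.0102 in a two-sided Fisher's exact test). In the whole replicate lists 97.3% (96.6 to 97.9) had a peak in all 3, against 42.1% of unthresholded promoter peaks without an exact match. The thresholded list was chosen by IDR from these same 3 replicates and holds the strongest pooled peaks. High shares in the replicate lists follow at least in part from that choice. Neither value can therefore exclude irreproducible calls. A degenerate sequence may account for some of them, since 9.73% matched with 1 mismatch against 5.39% of unthresholded promoter peaks, an odds ratio of 1.89 (1.58 to 2.26) that lies between the bounds set in advance. Recovery of transcribed genes of any kind also stays open: tRNA genes had a summit 1.56 times as often as random placements, with an interval of 0.988 to 2.31. The other noncoding classes, chosen after the results were seen, were mixed. Small nuclear RNA genes stood at 7.22-fold, small nucleolar RNA genes at 1.84-fold and ncRNA genes at 1.37-fold, while 0 of 99 rRNA genes had a summit. Transcription was not measured here.

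Summits in close pairs could be 1 site reported as 2 by the peak caller, or neighbouring sites with a sequence each. The weaker summit of 738 pairs within 300 bp carried the consensus with up to 1 mismatch within 50 bp in 3.39% of cases, less often than unthresholded peaks (5.74%), with an odds ratio of 0.575 (0.384 to 0.861). Single summits of matched signal carried it in 17.1% of cases, so that the weaker summits differed by -13.8 percentage points (-17.1 to -10.6), which argues against a sequence of its own at each. Splitting by the caller is thus a candidate explanation for these pairs, and counts of sites are given with and without merging for this reason.

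The peak at su(Hw) had rank 5 without a match to the consensus: 0 matches with up to 1 mismatch lay within 100 bp of the summit. This leaves a recognition sequence under the summit open, since the same search found no match at 49.9% of the strongest 613 peaks, and the absence was known when the test was written. Extra copies of the locus from the tagged transgene could raise signal there. The pooled list held 8 other summits within 10 kb, against a median of 6 and a highest value of 17 around the other 100 strongest peaks. A count of summits does not measure copy number, so extra copies of the locus from the tagged transgene can be neither excluded nor favoured. The peak was 1158 bp wide, and 1% of the other 100 were as wide.

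TATCGATA, a sequence known from promoters of housekeeping genes, was at 4.87% of the weaker and 3.52% of the stronger 2671 merged sites. GGTCACAC was at 4.31% and 1.39%, and the su(Hw) consensus with up to 1 mismatch at 16.5% and 31.0%. TATCGATA and GGTCACAC were picked because they were frequent in the weaker part of this list, so their differences are given as values without a test. Each TATCGATA also counted as a BEAF-32 pair, so its values are not separate from those of the pairs.

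Annotated gypsy elements, a retrotransposon whose insulator binds su(Hw), did not stand out: 3 of 22 copies had a summit within 500 bp, 0.888 times the random level with an interval of 0.189 to 2.27. With 22 copies this decides little. The annotated copies ranged from 46 to 7466 bp in length, so short fragments counted beside long copies. Whether each holds the insulator was not examined.

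The peaks whose ranks differed most between replicates lay at CG42699, CG12516, imd, Gga and eIF5B. The peak at imd had rank 293 in replicate 3 and no summit within 200 bp in the lists of replicates 1 and 2. That at CG42699 had rank 97 in replicate 1 and no summit within 200 bp in the others. A lack of a match at 200 bp does not mean that no peak lay further away. The strongest 1000 peaks of each replicate, merged within the replicate, made 945, 931 and 914 sites in replicates 1, 2 and 3. Of these, 0 lacked a peak within 1 kb in another replicate's list. This holds for the distance of 1 kb. Each peak named above ranked within the strongest 1000 of at least 1 replicate, so its merged site was among those searched. The other replicates thus had a peak within 1 kb of these sites, and the missing matches at 200 bp were not missing peaks at 1 kb. Whether the further peaks mark the same site was not tested. Within 200 bp, on average 99.55% of the strongest 1000 peaks had a peak in the whole list of another replicate. Tests written for strong peaks missing from another replicate had no sites at 1 kb, and they were not run on the peaks unmatched at 200 bp.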
